A study of Mus musculus with 6 samples.

How the data were processed

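Total RNA of 6 samples was hybridised to microfluidic miRNA arrays by a service provider, from 1 µg per sample, per the labels' protocols. The scanner files give 1 median brightness per spot as a linear intensity with no background column, per the file headers. The deposited value table holds 1 linear intensity per probe, and its lowest values near 0 and its column medians, between 11.9 and 14.1, show that the authors subtracted background and scaled it; the method is not given in the sources used here. Its values rank like the scanner values, and it was used as an alternative. All of its sample columns were matched to samples. Each array held 3968 spots, 168 of them controls.

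Spot intensities were background-corrected with normexp (offset 50, fitted on all spots), quantile-normalized over the mouse miRNA spots, put on the log2 scale and averaged over the 2 spots of a probe, with limma 3.58.1 in R 4.3.3. Pairs of spots correlated between 0.983 and 0.989 on each array, and no pair of arrays held the same values; array pairs correlated between 0.93 and 0.98 over the tested probes. A probe counted as detected on an array if its mean signal exceeded the 95th percentile of the 4 blank spots, since the files have neither a local background nor a detection column, and it was tested if detected on at least 3 of 6 arrays; 1181 probes were tested and 671 were detected on all 6. There were 12 probes that target more than 1 named miRNA. Groups were compared with lmFit and eBayes over all 6 arrays and Benjamini-Hochberg adjustment at 0.05. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists with at least 3 tested probes. A probe joined a list if its name, without arm and copy number, equalled a listed name. Names with a further letter stayed out, except for miR-466, miR-297, miR-467 and miR-669, where any letter counted. No miR-21, miR-142 or miR-126 probe was among the tested members of the lists that name them. The groups' detection counts were compared with an exact permutation test. Log2 differences are db/db minus db/+.

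The groups, tests, lists, a first set of alternative settings and the rule for named miRNAs were fixed before the data were examined, with the blank-spot percentile as the detection rule for files of this kind. Further settings were added after seeing the data and are named as such in the closing section. The rule took the 8 probes per direction with the largest change among those that passed with groups that do not overlap, filled up by the smallest unadjusted p where fewer passed, which here was every place. It added every tested miR-200 probe, the 4 miR-466 probes and the 2 probes of each other list with the smallest p, and the 5 brightest probes, 54 in all.

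The steps were tested on simulated arrays for db/db versus db/+, with 200 probes changed, 190 of them among the 1193 tested. Of the tested probes changed 1.5-fold 18.2% were recovered, of those changed 2-fold 67.2% and of those changed 4-fold 93.3%. Of the calls 5.13% were false. The shares were not split by signal. Of the 200 changed probes 190 passed the detection filter, so the changed probes were mostly probes read above the blanks, and the shares hold for such probes. The shares therefore do not give the recovery of dim probes close to the blanks, the miR-200 family among them, which may be lower. Simulated probes varied independently, so the correlation within lists was not part of that test.

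Alternatives covered normalization, offset, the authors' value table, the probe filter, the variance model, array weights, leaving out each array, and the list test. Plain subtraction of a local background and foreground alone had been planned only for files with a background column, so blank-spot subtraction and uncorrected signal stood in for them. Genome coordinates are not given, because no genome build is named in the sources used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.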

Results

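MicroRNA levels were measured in bone marrow-derived progenitor cells of db/db mice, which lack a working leptin receptor and develop obesity and type 2 diabetes, and of their db/+ littermates. Marrow mononuclear cells had been kept in endothelial growth medium for 4 days, washed free of non-adherent cells and grown for another 3 days before RNA was taken. There were 3 arrays of db/+ cells and 3 of db/db cells, each hybridised with 1 Cy5-labelled sample. The arrays carried 1900 mouse miRNA probes in 2 spots each, and 4 blank spots. The median scanner signal of the miRNA probes lay between 49.5 and 104.4 on the 6 arrays, close to the median of the blank spots, which lay between 39.1 and 97.2, so most probes were dim. The brightest probe of each array read between 18213 and 42991. The labels do not say that each sample came from a separate animal, so the p-values measure the spread between these samples. The number of arrays limits the precision of every value below.

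The first comparison asked which miRNAs differ between diabetic and control progenitor cells. No miRNA passed the test: of 1181 probes tested with limma, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.11. At an unadjusted p under 0.05 there were 59 probes, 34 higher and 25 lower in db/db cells, where 59.05 are expected by chance. The 3 values of one group lay wholly above those of the other for 114 probes, or 9.65% of those tested, where chance gives 10%. The values that follow for single miRNAs are therefore measurements that did not pass.

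The probe nearest to the threshold was miR-6238, with a normalized log2 intensity of 7.44 ± 0.48 (SD, n = 3) in db/+ cells and 10.29 ± 0.60 (SD, n = 3) in db/db cells. Its log2 difference was 2.85 with a standard error of 0.35 and a limma adjusted p of 0.11, and it was higher on all 3 db/db arrays than on any db/+ array. The bright probe for miR-341-5p, encoded in the imprinted Dlk1-Dio3 region, measured 12.96 ± 0.41 (SD, n = 3) in db/+ and 14.49 ± 0.39 (SD, n = 3) in db/db cells, a log2 difference of 1.53 with a limma adjusted p of 0.32. Further probes with higher readings in db/db cells were miR-711 with a log2 difference of 1.12, miR-669e-5p with 0.91, miR-466h-5p with 0.69, miR-466j with 0.66, miR-7034-3p with 0.51 and miR-1187 with 0.38. The miR-665-3p probe had a log2 difference of 2.98 with a standard error of 0.96, and its db/db values spread widely, at 10.28 ± 2.03 (SD, n = 3).

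Among lower readings, miR-181c-5p, a member of the miR-181 family known from lymphocytes, measured 9.05 ± 0.25 (SD, n = 3) in db/+ and 7.72 ± 0.26 (SD, n = 3) in db/db cells, a log2 difference of -1.33 with a limma adjusted p of 0.14. The probe for miR-92a-3p, of the miR-17-92 cluster, had a log2 difference of -0.86. Those for miR-182-5p, miR-511-3p, miR-6945-5p, miR-151-5p, miR-16-2-3p and miR-223-5p had log2 differences of -0.85, -0.68, -0.66, -0.52, -0.48 and -0.47. The miR-6945-5p values of the groups overlapped. In 6 of the alternative settings between 1 and 7 probes passed, and miR-6238 was among them each time.

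**Figure D1:**
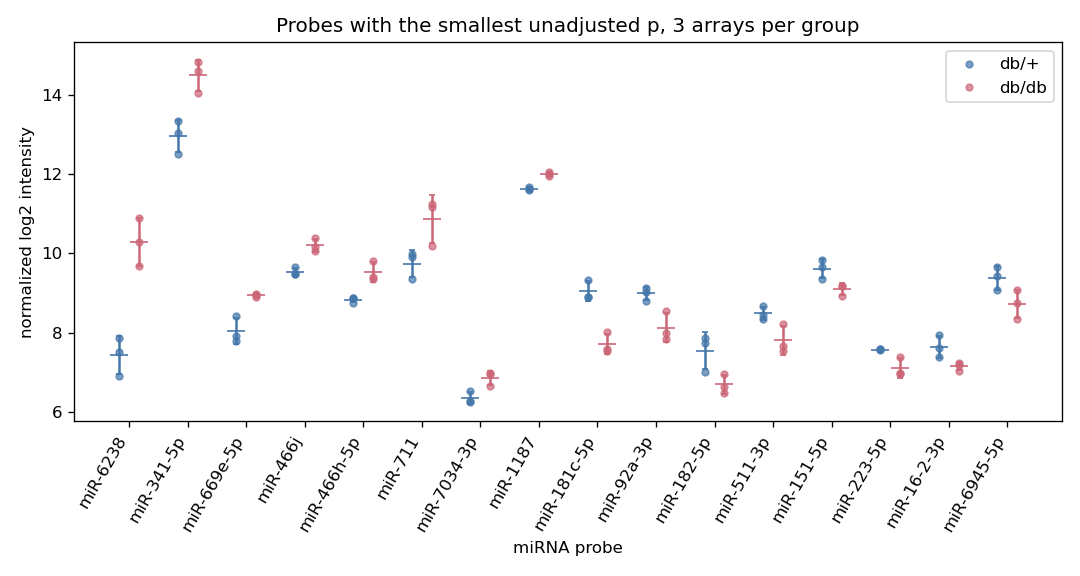
Normalized log2 intensity (vertical axis) of the 16 probes with the smallest unadjusted p, 8 per direction (horizontal axis). Points are single arrays, and bars are the mean and SD of 3 arrays per group; no probe passed the adjusted threshold, and miR-6238 shows the widest gap, 7.44 against 10.29.

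The probes with the highest signal were miR-709, miR-690, miR-6239, miR-5126 and miR-29a-3p, with mean log2 intensities in db/+ cells of 14.85, 14.56, 13.89, 14.06 and 14.04. Their log2 differences were -0.38, -0.16, 0.65, -0.14 and -0.12, and none passed.

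The miR-200 family, known from epithelial cells as repressors of Zeb1 and Zeb2, was one of the families the study chose on these samples, so its direction here is not independent evidence. It was close to background: of 10 probes on the array 4 were tested, and no probe of the family read more than 2.13 times the median blank of its array. The log2 differences were -0.05 for miR-200a-5p, 0.01 for miR-200b-3p, -0.15 for miR-200b-5p and 0.06 for miR-200c-3p, with a list median of -0.02; with 75th percentile scaling, which moved the median of all tested probes from -0.02 to -0.18, miR-200b-3p and miR-200c-3p had -0.21 and -0.14. The list did not pass, with a camera adjusted p of 0.92, and 0 members passed over all probes or adjusted over the list alone. No difference in this family was detected, at a signal close to the blanks and with standard errors of 0.13 to 0.21 for the 4 tested probes. Their group means, between 73.5 and 102.6 on the linear scale, include the added offset of 50. Log2 differences and their standard errors are therefore compressed for these probes, and do not tightly bound the change in miRNA level.

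The miR-466 family, related miRNAs of both hairpin arms, was likewise chosen by the study on these samples. Its list took every probe numbered miR-466. The family is known from a cluster in an intron of Sfmbt2, but the genomic place of its members was not checked. Of 25 tested probes 22 had a log2 difference above 0, with a median of 0.25. The 11 probes for 5p arms had a median of 0.66 and the 9 for 3p arms had 0.12. The list passed camera with a preset correlation, at an adjusted p of 1.1e-05. It did not pass with an estimated correlation, at an adjusted p of 0.78. Over all tested probes 0 members passed, and adjusted over the list alone 2 did, miR-466j and miR-466h-5p, which is not independent evidence. Members miR-466f-5p and miR-466d-5p had log2 differences of 0.86 and 0.59. The call ended without db/+ replicate 3, where the median was 0.027, the mean 0.19 and the adjusted p 0.21. It also ended with all its probes averaged into 1 value, 0.35, at an adjusted p of 0.29, a test that 1 value could hardly pass. Without db/+ replicate 2 and without db/db replicate 1 the median was 0.41 and 0.42. The Sfmbt2 list, 39 tested probes numbered miR-297, miR-467 and miR-669 after that cluster, had a median of 0.08. Its camera adjusted p was 0.026 with the preset correlation and 0.78 with an estimated correlation. The call ended without db/+ replicate 3, db/db replicate 2 or db/db replicate 3, with medians of -0.082, -0.019 and 0.036, and the median was 0.22, 0.19 and 0.19 without db/+ replicate 1, db/+ replicate 2 or db/db replicate 1. It also ended over probes detected on all 6 arrays and with the blank median subtracted, at medians of 0.061 and 0.12 and adjusted p of 0.074 and 0.066. Averaging probes of the same number, whatever their letter or arm, into 3 values ended it too, at a median of 0.23 and an adjusted p of 0.32. Their examples miR-669e-5p and miR-297a-5p had log2 differences of 0.91 and 0.47.

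**Figure D2:**
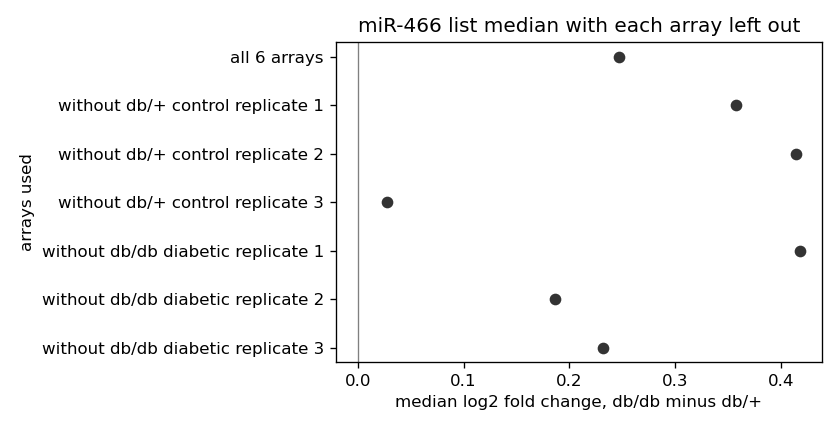
Median log2 difference, db/db minus db/+, of the 25 tested miR-466 probes (horizontal axis) with all 6 arrays and with each array left out (vertical axis). Each point is 1 fit; the median is 0.25 with all arrays and 0.027 without db/+ replicate 3.

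Besides, 4 lists passed camera with the preset correlation in the lower direction, with 0 members passing in any of them. None of the 4 passed camera with an estimated correlation, at an adjusted p of 0.78 each. Mesenchymal and stromal miRNAs had a median of -0.18 over 26 probes, 19 below 0 and 7 above, and an adjusted p of 0.015, with miR-152-3p at -0.45 and miR-214-3p at -0.59. Megakaryocyte and platelet miRNAs had a median of -0.13 over 18 probes, 14 below 0 and 4 above, and an adjusted p of 0.027, with miR-130a-3p at -0.53. Myeloid and macrophage miRNAs had a median of -0.30 over 9 probes, 7 below 0 and 2 above, and an adjusted p of 0.027, with miR-511-3p and miR-223-5p as above. The other arm of the latter, miR-223-3p, named after its value was seen, went the opposite way, at 0.55 with a standard error of 0.33, and it is in the megakaryocyte list too. That list also shares miR-155-5p and miR-223-5p with the myeloid list, and miR-125b, miR-199a and miR-99a probes with the mesenchymal list. The calls of these lists are therefore not separate from each other. The myeloid list names miR-21 and miR-142 and the megakaryocyte list names miR-126, but no such probe was among their tested members. Epithelial miRNAs outside the miR-200 family had a median of -0.16 over 13 probes, 11 below 0 and 2 above, and an adjusted p of 0.041, with miR-182-5p as above and miR-192-5p at -0.45. Without db/+ replicate 3 no list of the 23 passed. In the order given, the medians without that array were -0.18, -0.13, -0.28 and -0.079. All 4 calls also ended without db/db replicate 1, with medians of -0.15, -0.14, -0.28 and -0.20, and without db/db replicate 3, with -0.11, -0.17, -0.20 and -0.086. Without db/+ replicate 2 the megakaryocyte and myeloid calls ended, with -0.20 and -0.39 and an adjusted p of 0.051 each, and without db/db replicate 2 the megakaryocyte and epithelial medians were -0.20 and -0.25. All 4 also lost the call with 75th percentile scaling, at adjusted p from 0.091 to 0.31 and medians of -0.33, -0.31, -0.33 and -0.28 where all tested probes had -0.18. They lost it with no normalization between arrays, at adjusted p from 0.054 to 0.25 and medians of -0.20, -0.18, -0.19 and -0.14. With the blank median subtracted they lost it at adjusted p from 0.10 to 0.23, with larger medians of -0.38, -0.50, -0.43 and -0.45 but an SD over all tested probes of 0.73 against 0.31. With cyclic loess the myeloid and epithelial calls ended, at medians of -0.21 and -0.076 and adjusted p of 0.074 and 0.10. Over probes detected on all 6 arrays the megakaryocyte, myeloid and epithelial calls ended, at medians of -0.24, -0.37 and -0.28 and adjusted p of 0.060, 0.060 and 0.086. The same 3 ended, with their medians as printed above, when same-numbered probes of the miR-466 and Sfmbt2 lists were collapsed, at adjusted p of 0.057, 0.057 and 0.082. They also ended, with the same medians, with the replicate number as a block, at adjusted p of 0.055, 0.072 and 0.072. The 5 SD filter ended the megakaryocyte and myeloid calls, at medians of -0.25 and -0.44 and an adjusted p of 0.060 each, and leaving out both end arrays of the first principal component ended the myeloid call, at -0.11 and 0.13. The count of passing lists was 6 with all arrays.

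The remaining 17 lists did not pass. Adjusted over their lists alone, miR-181c-5p in the lymphoid list had a limma adjusted p of 0.0030 and miR-341-5p in the Dlk1-Dio3 list 0.038. Neither passed over all probes. The other tested miR-181 probes lay between -0.28, for miR-181a-5p, and 0.14, for miR-181d-5p, with the opposite arm miR-181c-3p at 0.017. Medians were -0.08 for angiogenesis miRNAs, -0.12 for lymphoid miRNAs with miR-150-3p at -0.24, -0.19 for inflammation-induced miRNAs with miR-146a-5p at -0.44, and -0.17 for the miR-17-92 cluster and its paralogues with miR-92a-2-5p at 0.63. They were -0.08 for the miR-30 family with miR-30c-5p and miR-30a-3p at -0.27 and -0.24, -0.28 for erythroid miRNAs with miR-451a at -0.60, and -0.06 for endothelial miRNAs with miR-100-5p and miR-31-5p at -0.26 and -0.62. The endothelial and angiogenesis lists name miR-126, the lymphoid list miR-142 and the inflammation list miR-21. No such probe was among their tested members, so the endothelial median says nothing of miR-126. MiRNAs reported as substrates of IRE1, the endoribonuclease of the unfolded protein response that the study is about, had a median of -0.16 over 8 probes. Of these 5 were below 0, with miR-17-3p and miR-125b-5p at -0.37 and -0.26, and 3 above. That median was -0.0092 without db/+ replicate 3 and -0.087 without db/db replicate 2. The miR-29 family had a median of 0.11, with miR-29b-3p at 0.88 and a standard error of 0.53 and miR-29c-3p at 0.49. Medians were -0.08 for p53 and senescence miRNAs, -0.11 for the Dlk1-Dio3 region, whose mean was 0.07, and 0.00092 for insulin and obesity miRNAs with miR-143-3p at -0.44. ER stress miRNAs had a median of -0.06, with miR-346-3p and miR-204-3p at -0.10 and 0.13. The let-7 family had a median of -0.0010, with let-7e-5p and let-7f-2-3p at 0.43 and -0.27, and the miR-23-27-24 clusters had -0.02, with miR-27b-5p and miR-23b-5p at -0.27 and 0.11. Liver, muscle and neuron miRNAs, which the cultures should not hold, had a median of -0.12 and a mean of 0.0040. Of their 11 tested probes 7 were below 0 and 4 above, with miR-129-1-3p and miR-208a-5p at 0.33 and 0.40.

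Some of these 17 lists passed camera with the preset correlation in other settings. With the spike split of 3 and 3 as a block, described below, the miR-17-92, angiogenesis, miR-30 and let-7 lists did, at medians of -0.30, -0.13, -0.19 and 0.15. Without both end arrays of the first principal component the same 4 lists did, at -0.41, -0.17, -0.27 and 0.16, and the lymphoid, endothelial, p53 and insulin lists, at -0.12, -0.17, -0.20 and -0.16. Without db/+ replicate 1 the miR-17-92, angiogenesis, lymphoid, endothelial and miR-30 lists did, at -0.30, -0.11, -0.12, -0.14 and -0.18, and with no probe filter the miR-17-92, angiogenesis, lymphoid, endothelial and inflammation lists did, at -0.11, -0.079, -0.053, -0.063 and -0.12. The inflammation list also passed without db/db replicate 2, at -0.27. With an estimated correlation the adjusted p of these lists in these settings lay between 0.57 and 0.82. Without db/+ replicate 3 the miR-17-92 median was -0.0051, and without db/db replicate 3 the inflammation median was -0.035.

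The arrays also split by their spike controls. By PUC2PM-20B and a3-PUC2PM-20B, picked after their values were seen, db/+ replicates 1 and 2 and db/db replicate 2 were bright and the others dim. With that split as a block 0 probes and 8 lists passed, and miR-6238 had a log2 difference of 2.67, with 2.29 within the bright set and 3.06 within the dim set. The miR-466 median was 0.42 with the block, 0.24 within the bright set and 0.62 within the dim set. Of the 4 lower lists 3 had a median near 0 within the bright set, -0.01 for mesenchymal, -0.0024 for megakaryocyte and -0.04 for epithelial miRNAs, and the myeloid list had 0.17. Within the dim set the same lists had -0.29, -0.36, -0.47 and -0.43, and with the block the megakaryocyte and epithelial lists passed, at adjusted p of 0.039 and 0.023, and the mesenchymal and myeloid lists did not, at 0.064 and 0.084. With the block and an estimated correlation the megakaryocyte and epithelial lists had an adjusted p of 0.70 and 0.65. The bright set holds 1 db/db array and the dim set 1 db/+ array, replicate 3, so each value within a set, and each blocked value, rests on an arm of 1 array in each set. A split by all spike probes placed the arrays otherwise, with db/+ replicate 3 and db/db replicate 1 apart from the rest.

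The number of miRNA probes above the blank spots was compared to see whether the arrays differed in detection. It was 1266 ± 385 (SD, n = 3) in db/+ and 1152 ± 611 (SD, n = 3) in db/db cells, an exact two-sided permutation p of 0.70 where 3 against 3 arrays cannot go below 0.10. The counts were 971, 1125 and 1701 on the db/+ arrays and 1855, 851 and 751 on the db/db arrays. The sign of the difference changed with the detection rule.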

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

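Tests of the miR-6238 and miR-466 patterns below were chosen after the results were seen, except the counts over other splits. The requirement that a gap separate the groups array by array was added after a first version without it had argued against both UG-repeat binding and the precursors, and the interval on the detection ratio and the standard error on the blocked miR-466 value were added after those values were seen; without the latter the spike split had been argued against for miR-466. In data outside the comparisons, 1 of 24 control probes, the mismatch spike a3-PUC2MM-20B, read higher on every db/db array than on any db/+ array in the authors' value table, by 0.66 on the log2 scale. By chance 1.2 of 24 would do so, and the use of that table was settled after control values had been seen. In the scanner signal 3 control probes did, and 0 did after scaling to the 75th percentile.

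The higher miR-6238 reading was not tied to 1 array, since its log2 difference was at least 2.54 whichever array was left out. Blocking on the spike split picked after seeing it left 2.67 with a standard error of 0.34, and the all-probe split is balanced over the groups and so cannot move the value. The 9 tested probes that share 8 bases in a row with it, at any place in its sequence, had a median of 0.080 and at most 1.01. This argues against an RNA bound through those short stretches alone. Binding along more of the sequence was not tested by it and stays open. The difference between db/db and db/+ mice stays open as a hypothesis, and the probe did not pass the adjusted threshold among 1181.

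The higher miR-466 list may rest in part on 1 array: without db/+ replicate 3 its median was 0.027, though its mean was still 0.19. With each probe centred on its own mean, the list's median was -0.47 on that array, against 0.03 and 0.14 on the other db/+ arrays and -0.07, 0.25 and 0.18 on the db/db arrays. The group difference of the list's mean per array was 0.35 with a standard error of 0.21, and 0.44 with 0.20 with the spike split as a block, a value that rests on an arm of 1 array in each set and is too loose to exclude that split, which stays open. UG-repeat probes outside the lists had a median of 0.14 against 0.63 for UG-repeat miR-466 probes, with a two-sided permutation p of 6.0e-05 over probes that are not independent, but the gap did not separate the groups array by array, so UG-repeat binding stays open. The 5p arms exceeded the 3p arms of the same letter by 0.45 on average over 7 letters, with an exact sign-flip p of 0.031. The letters are related and were read on the same arrays, so that p measures a spread between letters, not between samples. The gap between arms too did not separate the groups array by array, so more of the precursors stays open.

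The spread of detection counts, with a highest over lowest count of 2.47, held its highest and its lowest count, 1855 and 751, among the db/db arrays. A difference by genotype cannot be told from these counts, since the exact permutation p was 0.70 and 3 against 3 arrays cannot go below 0.10. A rule without blank spots, 2 times the array median, gave a ratio of 1.59 with a 95% bootstrap interval of 1.48 to 1.70. That interval includes the bound of 1.5 set before it was seen. The ratio alone lies above that bound, so it was the interval that kept this open. Under that rule db/db replicate 1 and db/+ replicate 3, highest above the blanks at 1855 and 1701, had the lowest counts, 373 and 307. The order of the arrays therefore changed once the blank spots were not used. The ratio itself can neither exclude nor show the level of the 4 blank spots as the reason for the spread.

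With 10 splits of the 6 arrays into 3 and 3, a share under 0.05 is out of reach. The count of differential miRNAs was 0 in the real split and at most 0 in the others, so 10 of 10 gave as many. The count of shifted lists was 6 in the real split and at most 10 in another, and 5 of the 10 splits, the real one included, gave as many. Every other split passed between 2 and 10 lists with the preset correlation, so passing lists there is not particular to the real groups. The absolute miR-466 median was 0.25 in the real split and at most 0.39 in another, and 3 of the 10 splits, the real one included, gave as much. At an unadjusted p under 0.05, 3 of the other splits gave more probes than the 59 of the real one, the split along the spike controls and 2 that do not follow it.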

How the results depend on the processing

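The alternatives on uncorrected and blank-subtracted signal, both spike blocks, the 5 SD filter, the rules of 3 SDs and of 2 times the array median, and the fit without both end arrays of the first principal component were chosen after seeing the data. The count of differential miRNAs was 0 in the setting reported and 7 with 75th percentile scaling, which moved the median of all tested probes to -0.18, 1 with offset 16, 1 over probes detected on all 6 arrays, 1 with the 5 SD filter and 2 with trend and robust on. Leaving out 1 array gave between 0 and 3 probes, 3 of them without db/db replicate 2. The other alternatives run for this count gave 0. The count of lists was 6, and it was 2 with 75th percentile scaling, 4 with cyclic loess, 4 with the 5 SD filter and 2 with no normalization between arrays. It was 11 with no filter, 2 over probes detected on all 6 arrays, 0 with an estimated correlation and 0 with fry. With same-numbered probes of the miR-466 and Sfmbt2 lists averaged, whatever their letter or arm, it was 1. There the miR-466 list was 1 value, 0.35, and did not pass at an adjusted p of 0.29, a test that 1 value could hardly pass. The count was 1 with the blank median subtracted and 13 without the end arrays. Leaving out 1 array gave between 0 lists, without db/+ replicate 3, and 11 lists, without db/+ replicate 1, with 2 without db/db replicate 1 and 1 without db/db replicate 3. With the replicate number as a block, 0 probes and 3 lists passed. The mean difference in detection counts within pairs was -113.3, which equals the unpaired difference whatever the pairing. Deviations of same-numbered arrays correlated at -0.04, -0.0028 and 0.03. These values gave no sign that the numbers pair the samples, but so few arrays cannot exclude it. The difference in detection counts was -113.3, and it was 36.7 with 2 blank SDs, 83.0 with 3, 81.7 with 5 and 38.0 with 2 times the array median, and between -464.7 and 104.3 with 1 array left out. The cause of these changes was not tested, apart from fewer probes or arrays where a filter or array was changed. Median of the repeat spots equals their mean and was not run, and no slide or chip is given to block on. Signals near the blanks limit the dim probes, the miR-200 family among them.

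The sign of these values changed as follows; no single probe among them passed, while the Sfmbt2 list passed in the setting reported and with 75th percentile scaling, the let-7 list passed with the spike split of 3 and 3 as a block and without the end arrays, and the insulin and obesity list passed without the end arrays, at an adjusted p of 0.0070. With an estimated correlation, which was run in these settings after seeing the data, let-7 had an adjusted p of 0.65 with the block and of 0.69 without the end arrays, and insulin and obesity miRNAs had 0.57. The changes with 75th percentile scaling follow its shift of all tested probes to -0.18, and all but miR-200b-3p lie above that. With 75th percentile scaling, Sfmbt2 intron cluster without miR-466 had -0.060, miR-29 family had -0.096, insulin and obesity miRNAs had -0.15, miR-200b-3p had -0.21, miR-200c-3p had -0.14, miR-204-3p had -0.060 and miR-23b-5p had -0.078. With cyclic loess, miR-23-27-24 clusters had 0.016 and miR-200b-3p had -0.026. With no normalization between arrays, insulin and obesity miRNAs had -0.014, miR-200b-3p had -0.077 and miR-200c-3p had -0.0034. With offset 16, let-7 family had 0.0093. With the authors' value table, let-7 family had 0.00066 and miR-23-27-24 clusters had 0.0026. With no dim probe filter, insulin and obesity miRNAs had -0.0060 and ER stress miRNAs had 0.021. Over probes detected on all 6 arrays, Dlk1-Dio3 imprinted cluster had 0.087, liver, muscle and neuron miRNAs had 0.087 and let-7 family had 0.15. With no background correction, let-7 family had 4.6e-05. With blank median subtracted, insulin and obesity miRNAs had -0.023 and miR-200 family had 0.00082. With the spike split of 3 and 3 as a block, insulin and obesity miRNAs had -0.069, ER stress miRNAs had 0.017, miR-200 family had 0.0086, liver, muscle and neuron miRNAs had 0.050 and let-7 family had 0.15. With both ends of the first component left out, inflammation-induced miRNAs had 0.0019, miR-29 family had -0.15, insulin and obesity miRNAs had -0.16, ER stress miRNAs had 0.13, miR-200 family had 0.017, liver, muscle and neuron miRNAs had 0.0038, let-7 family had 0.16, miR-200a-5p had 0.026, miR-29b-3p had -0.065 and miR-29c-3p had -0.15. With blank median plus 5 SDs filter, liver, muscle and neuron miRNAs had 0.033 and let-7 family had 0.14. Leaving out 1 array, the lowest and highest values were -0.068 and 0.022 for insulin and obesity miRNAs, -0.13 and 0.079 for ER stress miRNAs, -0.063 and 0.055 for miR-200 family, -0.11 and 0.018 for liver, muscle and neuron miRNAs, -0.20 and 0.11 for let-7 family, -0.12 and 0.0074 for miR-200a-5p, -0.32 and 0.058 for miR-200b-5p, -0.20 and 0.011 for miR-346-3p, -0.082 and 0.22 for Sfmbt2 intron cluster without miR-466, -0.14 and 0.011 for angiogenesis miRNAs, -0.19 and 0.020 for lymphoid miRNAs, -0.40 and 0.13 for erythroid miRNAs, -0.14 and 0.014 for endothelial miRNAs, -0.13 and 0.053 for p53 and senescence miRNAs, -0.049 and 0.11 for miR-23-27-24 clusters, -0.075 and 0.052 for miR-200b-3p, -0.0034 and 0.15 for miR-200c-3p, -1.44 and 0.14 for miR-451a, -0.027 and 0.27 for miR-204-3p, -0.25 and 0.020 for miR-29a-3p, -0.19 and 0.040 for miR-30 family, -0.28 and 0.0047 for miR-690 and -0.016 and 0.23 for miR-29 family. With 1 array left out, 16 of the 54 named miRNAs moved by over 1.5 times without a change of sign, among them miR-29b-3p between 0.34 and 1.20, miR-29c-3p between 0.12 and 0.82, miR-31-5p between -0.87 and -0.26 and miR-214-3p between -0.78 and -0.29, as did 9 of the 23 lists. Some lists kept their call with a median moved by over 1.5 times. The miR-466 median was 0.15 with 75th percentile scaling, 0.42 with the blank median subtracted and 0.42 with the spike split of 3 and 3 as a block. The Sfmbt2 median was 0.036 with no filter, 0.24 with that block and 0.14 without the end arrays. The megakaryocyte median was -0.22 with offset 16 and -0.23 with that block. The mesenchymal median was -0.12 without the end arrays, and the myeloid median was -0.12 with no filter. The epithelial median was -0.094 with no filter, -0.35 with the 5 SD filter and -0.11 without the end arrays.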
